A study of Mus musculus with 2 samples.

How the data were processed

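MicroRNA-seq was run on 2 libraries of 1 group, left cerebral cortex of male B6CASTF1/J mice aged 4 days, per the labels. Each deposited table holds raw read counts per miRNA gene in 3 columns and was made from 1 library, with replicates not pooled. The assembly is mm10 and the annotation is GENCODE M21, per the text deposited with each table. The aligner and counter are not given in the sources used here. The 4 leading entries without a gene and the 3 count columns have the layout of STAR gene counts (either strand, own strand, opposite strand). In that layout reads placed at several sites are given to no gene, which can lower the counts of miRNAs made from several genomic copies. The entries without a gene (unplaced, several sites, outside miRNA genes, ambiguous) stayed out of library sizes and tests. On the own strand they were 18.4%, 46.1% and 5.55% of reads in the library labelled replicate 1 for the first 3 classes, and 6.11%, 39.8% and 1.47% in the library labelled replicate 2.

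Coordinates, symbols and overlapping genes came from GENCODE M21 on the same build, and all 2202 identifiers matched. The counts are per hairpin gene, so mature arms are not separated. The column of reads on the gene's own strand was used, because ligation-based small RNA libraries keep strand. Own-strand totals were 2999032 and 3577964 counts. The libraries were compared directly by an exact two-sided binomial test per gene against the TMM-scaled share of the libraries, over genes with at least 10 counts summed, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors were 1.63 and 0.615. The edgeR quasi-likelihood test needs replicates in each arm and was not run. The spread beyond counting error is the square root of the edgeR common dispersion. Log2 ratios of genes and list medians carry a prior of 1 CPM, except the ratio of summed muscle counts without Mir206, and are the library labelled replicate 2 over the library labelled replicate 1. Fold ratios and 95% intervals use total counts with no prior, from the exact Clopper-Pearson binomial interval. A gene with a count of 0 was given a bound from 3 counts per library.

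For 17 lists of miRNA genes the share of counts was computed per library. Lists with at least 3 tested genes (15 of 17) also got a median log2 ratio and its percentile among 10000 random lists of the same size matched on deciles of mean abundance. A list was called when outside the central 95% (2.5 to 97.5). No gene belonged to more than 1 list. The lists, the tests, the first set of alternatives and the rule for named genes were set before the data were examined. That rule takes the 20 genes with the highest mean CPM, up to 3 members per list by mean CPM, and the 5 largest log2 ratios each way among genes past the threshold with at least 100 counts. Other genes were named after their values were seen, as further examples or exceptions of a list or because they have copies (Mir132, Mir133b, Mir218-1, Mir124a and Mir9 copies, Mir770, Mir370, Mir29b-2, Mir223 and the copies of Mir1a, Mir133a and Mir138).

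Alternatives were unstranded counts, DESeq2 size factors, total counts, no filter (at least 1 count), a filter of 100 counts, a prior of 0.1 CPM, a pseudocount of 0.1, a negative binomial exact test with a coefficient of variation of 0.1 (edgeR), removal of the most abundant gene, and each library alone. Added after seeing the data were the removal of each list's most abundant member and a 4-fold minimum. The tests were run on simulated data for the comparison of the libraries (463 genes). The binomial test called 58.0% of genes changed 1.5-fold, 70.0% changed 2-fold, 88.0% changed 4-fold and 98.0% changed 8-fold, and 1.9% of unchanged genes. Those counts were Poisson draws from a shared profile, tested with total counts. They held no TMM step and no spread beyond counting error, so these rates do not give the error of the test in these libraries. Of 100 unchanged lists, made of random genes with independent log2 ratios, 8.0% lay outside the central 95%. An exact permutation test of 2 libraries cannot go below p = 0.5, so none was run across libraries. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.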

Results

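The data are microRNA (miRNA) sequencing libraries from the left cerebral cortex of B6CASTF1/J mice, per the labels. This strain is the first-generation cross of C57BL/6J and CAST/EiJ. Total RNA came from males aged 4 days, and RNA under 30 nt was selected. There is 1 group with 2 libraries, labelled biological replicates 1 and 2. The labels number the males differently but quote a single donor identifier for both, so how far the spread between these libraries is a spread between animals is not settled by the labels. The library labelled replicate 1 held 10029659 reads and the library labelled replicate 2 held 6800067. Reads given to a miRNA gene on its own strand numbered 2999032 (29.9%, exact 95% binomial interval 29.9 to 29.9) and 3577964 (52.6%, interval 52.6 to 52.7). Reads placed at several sites made up 46.1% and 39.8%, and unplaced reads 18.4% and 6.11%. Intervals and detection limits cover counting error only. They can understate even that error, because amplified reads without molecular identifiers are not independent molecules. A count of 0 allowed up to 1.00 CPM (counts scaled to library size) in the library labelled replicate 1 and 0.838 CPM in the other.

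**Figure D1:**
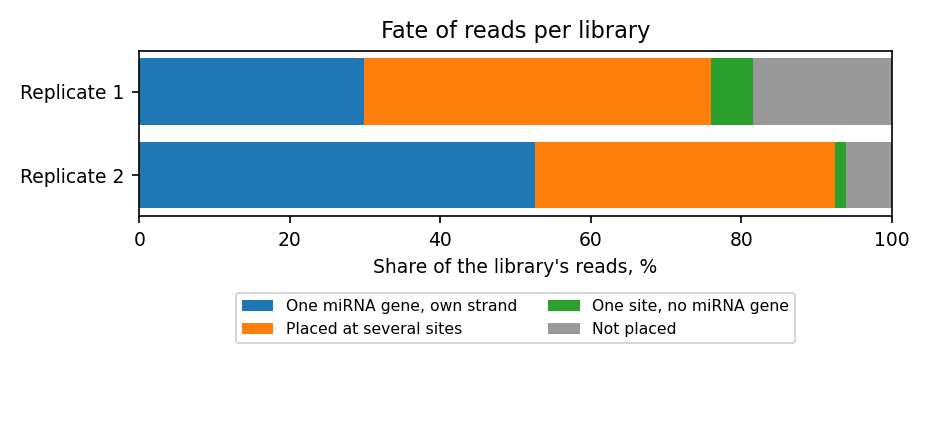
Share of each library's reads (x axis, %) given to a miRNA gene on its own strand, placed at several sites, placed at a single site outside miRNA genes, or not placed. The first class held 29.9% of reads in the library labelled replicate 1 and 52.6% in the library labelled replicate 2.

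Both libraries were rich in let-7 and in miRNAs of the imprinted Dlk1-Dio3 region of chromosome 12, but their most abundant genes differed. Mirlet7i led in the library labelled replicate 1 with 11.2% of counts, followed by Mirlet7g and Mirlet7b. Mir206, a skeletal muscle miRNA, led in the library labelled replicate 2 with 15.6% of counts, and it ranked 223 in the other. Of the 20 most abundant genes of each library, 8 were shared. The 10 genes with the highest mean abundance (Mirlet7i, Mir206, Mirlet7g, Mirlet7b, Mir99a, Mir127, Mir487b, Mir378a, Mir411 and Mir335) held 48.3% ± 6.46 of counts (SD, n = 2). They held 43.7% in the library labelled replicate 1 and 52.9% in the other. This set is not the top 10 of either library, which held 52.0% and 55.4%. Of the 2202 annotated miRNA genes, 291 had at least 10 counts in both libraries, 419 in the library labelled replicate 1 and 319 in the other. No count was seen for 1444 genes in either library.

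The only comparison the design holds is between the libraries of the same group, and it asks how alike they are. Muscle and Hox cluster miRNAs were far higher, and neuron-enriched miRNAs far lower, in the library labelled replicate 2. The muscle list took 0.00730% of counts (exact 95% interval 0.00637 to 0.00834) in the library labelled replicate 1 and 15.7% (15.7 to 15.7) in the library labelled replicate 2. Nearly all of it was Mir206, without which the list held 0.000233% and 0.0818%. The Hox list took 0.0228% (0.0212 to 0.0246) and 1.91% (1.90 to 1.93). The neuron-enriched list took 4.30% (4.28 to 4.32) and 0.132% (0.129 to 0.136). Reads placed at several sites are outside the gene counts, so the neuron-enriched and muscle shares may be too low. Both lists have members with copies, such as Mir124a and Mir1a, and the intervals do not cover that loss. The label of the library labelled replicate 2 names cortex, and each direction given here is between libraries as labelled.

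Of 463 genes with at least 10 counts summed, 370 differed between the libraries by an exact two-sided binomial test with TMM scaling (Benjamini-Hochberg adjusted, threshold 0.05). Of these, 188 were higher and 182 lower in the library labelled replicate 2, and 110 and 90 respectively differed at least 4-fold. With total counts in place of TMM, 417 genes passed, 122 higher and 295 lower, so that the share of higher calls moved from 50.8% to 29.3%. The median log2 ratio of all tested genes was -0.26 with TMM and -1.35 with total counts, and TMM lay 1.40 above total counts for an abundant gene. The test compares these 2 libraries with counting error alone and not conditions. Of 15 lists with a percentile, 5 (neuron-enriched, Dlk1-Dio3, Hox, muscle and sensory organ) lay outside the central 95% of random lists, where the nominal rate gives 0.75 and the rate seen for simulated unchanged lists gives 1.2. Both rates treat genes as independent. Genes of a single cluster, as in the Dlk1-Dio3 list, may move together, so these rates can be too low. Across the 463 genes the log2(CPM + 1) values correlated with a Pearson coefficient of 0.758 and a Spearman coefficient of 0.723, where genes are not independent replicates. The counts differed by a chi-square of 5667 per degree of freedom, so the libraries were not a single library deposited again and were counted as 2 samples. This value sets the libraries against counting error alone and does not measure how unusual the difference is. The edgeR biological coefficient of variation was 1.24.

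**Figure D2:**
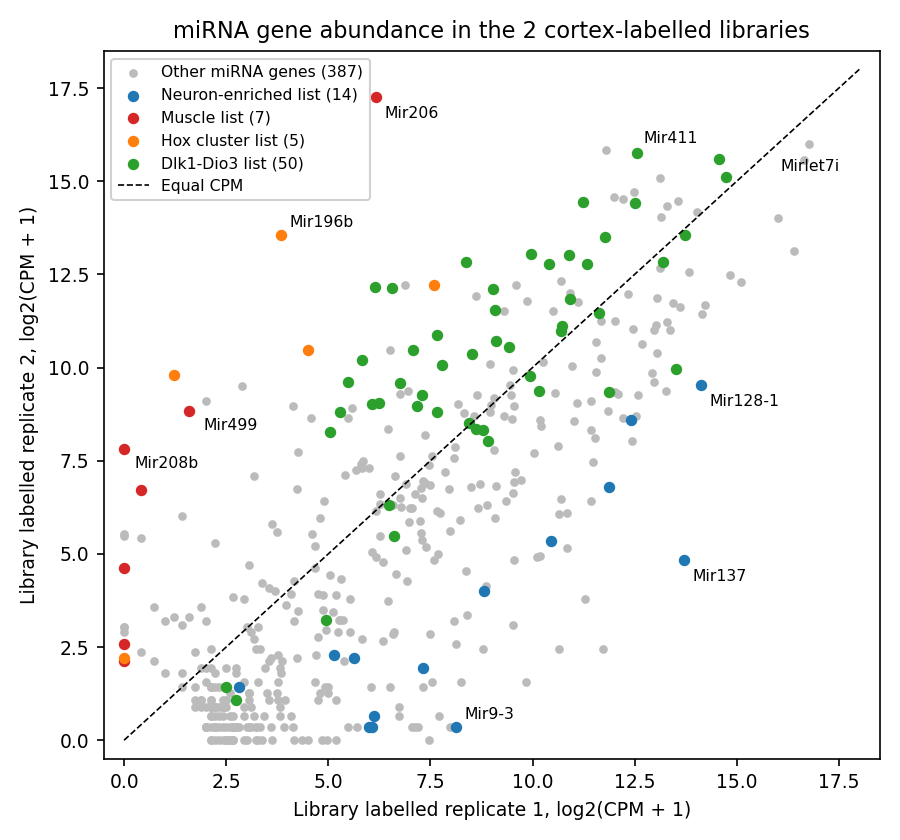
Abundance of 463 miRNA genes in the library labelled replicate 1 (x axis) and the library labelled replicate 2 (y axis), both as log2(CPM + 1), with 1 point per gene and a dashed line at equal CPM. Muscle genes (7) and Hox genes (5) lie above the line and the 14 neuron-enriched genes below it.

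Log2 ratios carry a prior of 1 CPM unless stated, which draws those of low counts towards 0, while folds and intervals carry none. All 7 tested muscle genes were higher in the library labelled replicate 2, by the test over all genes and when adjusted over the list alone (7). Their median log2 ratio was 7.15 (6.31 with total counts), at percentile 100 of 10000 random lists matched on abundance. With the 4 members at 0 in the library labelled replicate 1 set to the limit of 3 counts the median was also 7.15. Mir206 (ENSMUSG00000065559.1; chromosome 1, 20679010 to 20679082, in an exon of the long noncoding RNA Gm28653) had 212 and 559242 counts. That is 70.7 and 156302 CPM, a 2211-fold ratio (log2 11.09, 95% interval 10.92 to 11.31, total counts). Mir208b (chromosome 14, 54975700 to 54975776, in an intron of Myh7, a slow muscle and heart myosin gene) had 0 and 804 counts. With the count of 0 set to the limit of 3 counts the ratio was 224.6-fold. The lower end of the exact 95% interval lay below that ratio, at log2 7.51 (total counts). Mir499 (chromosome 2, 155622880 to 155622958, in an intron of Myh7b) had 6 and 1625 counts, a 227-fold ratio. Mir133b had 1 and 375 counts (log2 6.31, interval 5.81 to 13.60), which sets the list's median. Without Mir206, the remaining muscle genes had 7 and 2925 counts, a log2 ratio of 8.45 with no prior (interval 7.41 to 9.77, total counts). Copies of Mir1a share 28 nt and those of Mir133a 31 nt, so their counts of 0 to 85 are uncertain.

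All 5 Hox cluster genes, which lie among the Hox genes that pattern the hindbrain and trunk, were higher in the library labelled replicate 2, also when adjusted over the list alone (5). Their median log2 ratio was 7.33 (5.96 with total counts), at percentile 100. Mir196b (ENSMUSG00000065443.1; chromosome 6, 52230081 to 52230165, overlapping an exon of Hoxa9) had 40 and 42961 counts, a 900.2-fold ratio (log2 9.71, interval 9.37 to 10.30). Mir196a-2, in an intron of Hoxc5 on chromosome 15 (102973350 to 102973434), had 4 and 3206 counts. Mir10b (chromosome 2, 74726070 to 74726137, in introns of Hoxd3 and Hoxd4) had 576 and 17140 counts, and Mir10a (chromosome 11, 96317165 to 96317274) had 65 and 5063.

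Of the 14 tested neuron-enriched genes, 13 were lower in the library labelled replicate 2, 0 were higher and 1 (Mir218-1, with 18 and 6 counts) did not pass; with total counts 14 were lower. Adjusted over the list alone, 13 passed. The median log2 ratio was -3.70 (-5.09 with total counts), at percentile 0. Mir137 (ENSMUSG00000065569.2; chromosome 3, 118433857 to 118433929, in an exon of the noncoding RNA Gm26871) had 40242 and 99 counts, or 13418 and 27.7 CPM (log2 -8.87, interval -9.22 to -8.64, total counts). Mir128-1 (chromosome 1, 128202361 to 128202430, in an intron of R3hdm1) had 53592 and 2623 counts, and Mir128-2 (chromosome 9, 112118636 to 112118711, in an intron of Arpp21) 16271 and 1379. Mir132, an activity-regulated neuronal miRNA, had 11179 and 391 counts. Mir9-3 (chromosome 7, 79505264 to 79505353, in an intron of Mir9-3hg) had 837 and 1 counts, a log2 ratio of -7.77 (interval -15.27 to -7.48, total counts). The 3 Mir124a copies had 8, 3 and 1 counts in the library labelled replicate 1 and 0 in the other. They share at least 31 nt, so counts for this abundant neuronal miRNA are uncertain, as are those of the Mir9 copies, the Mir128 copies (which share 23 nt) and the Mir138 copies (24 nt).

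**Figure D3:**
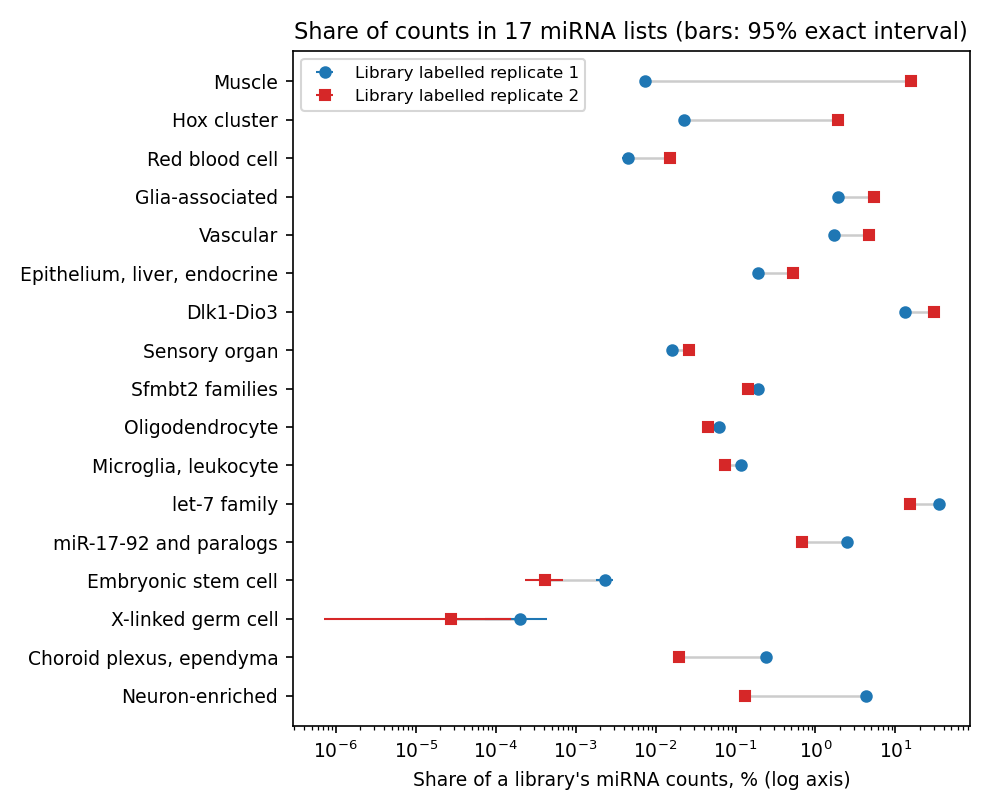
Share of a library's miRNA counts (x axis, %, log axis) in each of 17 lists (y axis), with circles for the library labelled replicate 1, squares for the library labelled replicate 2 and bars for the exact 95% binomial interval. The muscle list held 0.00730% and 15.7% and the neuron-enriched list 4.30% and 0.132%.

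The Dlk1-Dio3 list took 13.2% and 30.0% of counts, beside the muscle share of 15.7% in the latter library. Of its 50 tested genes, 44 were higher and 2 lower in the library labelled replicate 2 (34 and 14 with total counts; 46 adjusted over the list alone). The median log2 ratio was 3.07 (1.66 with total counts), at percentile 100. Mir411 (chromosome 12, 109710175 to 109710256) had 18175 and 198300 counts, a 9.14-fold ratio. Mir127 (109592846 to 109592915 on the same chromosome, opposite to an exon of Rtl1) had 73218 and 175530, and Mir487b had 81453 and 127077. The genes that were lower with TMM were Mir770, with 34832 and 3565 counts, and Mir370, with 11211 and 2306.

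The let-7 family, whose members rise as tissues mature, took 35.0% and 15.1% of counts. With TMM 7 of 12 tested genes were higher and 5 lower, and with total counts 1 was higher and 11 lower (12 passed with TMM when adjusted over the list alone), and the median log2 ratio was 0.43 with TMM and -0.97 with total counts (percentile 37.0). Mirlet7b (chromosome 15, 85707319 to 85707403, in an exon of Lncppara) was lower under both scalings, with 259290 and 32213 counts. Mirlet7i had 336931 and 234367 counts (log2 0.63 with TMM, -0.78 with total counts), so its direction depends on the scaling, and Mirlet7g likewise (0.33 and -1.08). The miR-17-92 list and its paralogous clusters, known from proliferating cells, took 2.46% and 0.685%. Of 13 tested genes 9 were higher and 3 lower with TMM, and 4 higher and 6 lower with total counts (12 adjusted over the list alone), with a median of 1.07 (-0.05 with total counts; percentile 88.3). Mir17 (30006 and 8526 counts) and Mir93 (25213 and 4757) were lower under both scalings.

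Lists for other brain and non-neural cells differed in direction, in the same libraries in which the muscle share was 0.00730% and 15.7%. Vascular miRNAs took 1.71% and 4.70% of counts, and 3 of 3 were higher in the library labelled replicate 2 (3 adjusted over the list alone; median log2 ratio 2.33, 0.93 with total counts; percentile 72.2). Endothelial Mir126a, in an exon of Egfl7, had 35984 and 81797 counts, and Mir143, abundant in smooth muscle, had 14193 and 84860. Glia-associated miRNAs took 1.90% and 5.45%, with 8 higher and 1 lower of 11 (6 and 4 with total counts; 9 adjusted over the list alone; median 2.04, 0.64 with total counts; percentile 97.2). Mir23a had 17170 and 96042 counts, while Mir29b-2, the lower member with TMM, had 16 and 0. A higher share of this list does not by itself show more glia, and which cells its reads came from was not tested. Choroid plexus and ependyma miRNAs took 0.239% and 0.0198%. Of 5 tested, 3 were lower and 1 higher with TMM, and 4 and 1 with total counts (4 adjusted over the list alone; median -1.50, -2.89 with total counts; percentile 10.1). Mir449a, a miRNA of multiciliated cells in an intron of Cdc20b, had 3306 and 104 counts.

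Red blood cell miRNAs took 0.00453% and 0.0153%, and 3 of 3 were higher in the library labelled replicate 2 (3 adjusted over the list alone; median 2.91, 1.54 with total counts; percentile 95.9). Mir451a had 34 and 196 counts. Microglia and leukocyte miRNAs took 0.118% and 0.0740%, with 4 higher and 2 lower of 6 with TMM, and 3 and 3 with total counts (6 adjusted over the list alone; median 0.93, -0.47 with total counts; percentile 72.8). Mir223 had 151 and 546 counts, and Mir150 had 1208 and 267. The oligodendrocyte list took 0.0616% and 0.0454%, with 1 higher and 1 lower of 3 with TMM, and 0 and 3 with total counts (2 adjusted over the list alone; median -0.70, -1.88 with total counts; percentile 44.8). Mir219a-2, lower under both scalings, had 314 and 3 counts (log2 -5.85, interval -9.25 to -5.40, total counts). Mir338 had 1491 and 1610 counts and passed as higher with TMM (log2 1.26), but its ratio was -0.14 with total counts.

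Epithelial, liver and endocrine miRNAs took 0.188% and 0.516%. Of 11 tested, 9 were higher and 1 lower (3 and 4 with total counts; 10 adjusted over the list alone; median 1.16, -0.23 with total counts; percentile 85.5). Epithelial Mir205 (chromosome 1, 193507463 to 193507530) had 19 and 2588 counts, a 114-fold ratio, and Mir203, a skin miRNA, had 2780 and 12608. The sensory organ list took 0.0160% and 0.0265%, with 3 of 3 higher with TMM and 2 with total counts (3 adjusted over the list alone; median 3.08, 1.70 with total counts) at percentile 99.5. That call ended without the filter on low counts, at percentile 94.8, and Mir183 had 353 and 417 counts, a log2 ratio of -0.01 with total counts. The imprinted Sfmbt2 families took 0.191% and 0.142%, with 5 higher and 2 lower of 8 with TMM, and 0 higher and 6 lower with total counts (7 adjusted over the list alone; median 0.44, -0.95 with total counts; percentile 58.6), and Mir467d had 2111 and 2198 counts. Embryonic stem cell clusters took 0.00230% and 0.000419%, and 2 of 2 tested genes (Mir302d, with 37 and 5 counts, and Mir302a, with 20 and 2) were lower (2 adjusted over the list alone). X-linked germ cell clusters took 0.000200% and 2.8e-05%, and 0 of their genes had enough counts to be tested.

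The 5 lowest log2 ratios among genes with at least 100 counts belonged to Mir92b, Mir137, Mir7b, Mir383 and Mir9-3. Mir92b (chromosome 3, 89227116 to 89227198) had 10118 and 16 counts, Mir383 (chromosome 8, 38252133 to 38252202, in an intron of Sgcz) 4802 and 16, and Mir7b 2743 and 7. The 5 highest belonged to Mir206, Mir196b, Mir196a-2, Mir208b and Mir499. Mir378a (chromosome 18, 61397835 to 61397900, in an intron of Ppargc1b, a coactivator of mitochondrial genes) had 10690 and 208475 counts, a 16.4-fold ratio with total counts. Mir335, in an intron of the imprinted gene Mest, had 26818 and 123752. Mir139, in an intron of Pde2a, had 87343 and 20657 counts, and Mir744 had 105904 and 18032. Mir99a was lower under both scalings, with 197009 and 58624 counts.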

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

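The opposite-strand test, the run lengths used to define shared sequence and the share of copies with enough counts for testing were chosen after the values were seen. The comparison of genes with and without copies was planned.

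The column of reads on the strand opposite to a miRNA gene was left out of the main measurement. It held 169860 counts in the library labelled replicate 1 and 424455 in the library labelled replicate 2, above the 3 counts that a count of 0 allows. At genes with no annotated miRNA gene on the other strand it held 115 and 43. Unstranded counting left 169744 and 424395 reads ambiguous between genes, close to the opposite-strand totals. Nearly all opposite-strand reads were therefore also counted on the own strand of an overlapping miRNA gene. In the unstranded counts, 26 genes with at least 100 counts kept under 0.1 of their own-strand counts, which removed 5.66% and 11.9% of all counts. Of these 26 genes, 26 overlap a miRNA gene on the opposite strand, against 0 of 269 other genes at that depth, so reads falling on overlapping miRNA genes may account for the loss. No biological explanation was tested.

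Reads placed at more than 1 site lay outside the gene counts and made up 46.1% of the library labelled replicate 1 and 39.8% of the library labelled replicate 2. If they were lost to miRNAs with several copies, such genes could be lower, and tested genes sharing 20 nt with another miRNA gene had a median mean CPM 0.868 times that of the others. That ratio was 1.15 with a run of 18 nt and 0.612 with 22 nt, so its outcome turns on the run length. It also covers only genes with at least 10 counts summed, so copies that lost most of their reads would be left out. For both reasons, low counts from shared reads and a true lower level cannot be told apart. Of the genes sharing 20 nt, 9.04% had at least 10 counts, against 32.6% of the others, and the 3 Mir124a copies had 8, 3 and 1 counts in the library labelled replicate 1. No biological explanation was tested.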

How the results depend on the processing

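No paired analysis was possible because the design has 1 group. The 4-fold minimum and the removal of a list's top member were chosen after the data were seen. Of 84 alternatives for list ratios, 77 kept direction and side of the limits. With total counts the medians of let-7 (-0.97), miR-17-92 (-0.050), Sfmbt2 (-0.95), microglia and leukocyte (-0.47) and epithelial (-0.23) lists turned negative, as the lower scaling of the library labelled replicate 2 implies, and let-7 reached -0.0013 with the 100-count filter. The sensory list lost its call with no filter (median 3.01, percentile 94.8); the cause was not tested. Differing genes numbered 364 with DESeq2 factors, 417 with total counts, 345 with the negative binomial test and 200 at least 4-fold apart (fewer by construction); this count needs both libraries. Genes with at least 1 count in both numbered 539, and single libraries gave 319 to 419 detected genes and 52.0 to 55.4% in the top 10 genes. The coefficient of variation was 1.23 (unstranded), 1.24 (DESeq2), 1.33 (total counts), 1.25 (no filter) and 1.27 (100 counts). Pearson was 0.842 (no filter) and 0.547 (100 counts), and Spearman 0.568 (100 counts); the causes were not tested. For list shares, each library alone (34 alternatives) cannot move the mean by 1 SD with n = 2, so that comparison is void, and the shares per library stand in the report. Of the other 51, 6 moved the mean by over 1 SD and 19 by over 1.5-fold, 16 of the latter without the top member. Unstranded counts gave 0% for oligodendrocyte and 0.00104% for red blood cell miRNAs, and 1.64% in place of 3.21% for vascular miRNAs. Without the top member, the shares were 0.101% (Sfmbt2), 0.00610% (oligodendrocyte), 0.0582% (microglia and leukocyte) and 0.00954% (sensory), and with libraries far apart (under 1 SD) the muscle mean was 0.0410% in place of 7.86% and the Hox mean 0.366% in place of 0.967%. Depth limits genes near 3 counts.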

Other observations

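These gene groups were chosen after their values were seen. The X-linked miRNA cluster from Mir450b to Mir322 (chromosome X, 53047997 to 53054349) was higher in the library labelled replicate 2 in all 7 genes measured, under both scalings. Mir322 had 12134 and 86819 counts, Mir351 2305 and 17014, Mir542 270 and 5091 and Mir503 321 and 2234, with log2 ratios of 2.58, 2.63, 3.97 and 2.53 with total counts and larger ones with TMM. Mir214 and Mir199a-2, neighbours on chromosome 1 and abundant in mesenchymal cells, had 347 and 17140 counts and 0 and 155 counts.

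Several miRNAs outside the neuron-enriched list were lower in the library labelled replicate 2 under both scalings. Mir135b had 1328 and 16 counts and Mir135a-1 527 and 0. Mir7-2 had 435 and 1 counts, and Mir7-1 300 and 75. In the Mir181 family, Mir181d had 29533 and 2379 counts and Mir181c 12342 and 2319, while Mir181a-2 (101 and 35) and Mir181b-1 (85 and 37) did not pass with TMM (adjusted p = 0.224 and 0.936, exact binomial test). Mir296 and Mir298 on chromosome 2 had 24296 and 2815 counts and 31402 and 7315.

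The muscle, Hox and neuron-enriched lists were singled out after their values were seen, as were the GC correction, the mixture bound and the test for another tissue. The GC correlation and the test for other cell types were planned. The test for another tissue asked for the same list pattern that prompted it, so its outcome was fixed in advance and adds no support. A GC trend is argued against as the whole cause, since a quadratic trend in hairpin GC removed 4.34% of the variance of the log2 ratio and left the muscle, Hox and neuron-enriched medians at 7.08, 6.15 and -3.79, while a part of it cannot be told apart from other differences because the correlation with GC (-0.229) lies between the bounds set for and against it. Muscle RNA is a candidate source, since the muscle list lay at percentile 100, but muscle mixed into a mainly cortical library is argued against: pooled over its genes, the neuron-enriched list kept 3.08% of its share in the library labelled replicate 1, with a range over the 13 genes of at least 100 counts there from 0.10% (Mir9-3) to 11.5% (Mir218-2), under the 50% that mainly cortex needs if cortex has a like profile in both. A library of another tissue, such as skeletal muscle of the trunk or limb, under the cortex label may therefore explain the pattern, given 15.7% of counts in the muscle list, led by Mir206 at 559242 counts, with Hox miRNAs also high, against 1 muscle gene with at least 10 counts in the library labelled replicate 1; where such a library came from was not tested. A biological difference between the animals, if the libraries came from separate animals, was not tested. Such a difference stays open because no other cortex library gives its spread, though it would have to include a 485-fold lower Mir137 and a 2211-fold higher Mir206.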
